A study of Mus musculus with 6 samples.

How the data were processed

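RNA-seq libraries were made with Smart-seq2 from 200 sorted bone marrow stem cells each, and sequenced with paired 150-bp reads on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.6, HISAT2, featureCounts, DESeq2 and the mouse genome build mm10, with no role or order, and the gene annotation release and the strand setting are not given in the sources used here. The series design also names chromatin accessibility data, which are not analysed here.

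The deposited table holds 1 value per gene and library for 11108 genes and 6 libraries. The unit is a signal that the authors deposited as gene read counts divided by 1 size factor per library, called normalised read count here. This was worked out from the values: 100% of them are whole multiples of the value of 1 read in their library, within a tolerance of 0.001 reads, so that whole reads were recovered. Size factors recomputed from the recovered reads by the median-of-ratios method of DESeq2 equalled those in the table, from 0.922 to 1.22. Each listed gene has reads in at least 4 of the 6 libraries (8304 genes in all 6, 1777 in 5 and 1027 in 4), so a gene read only in the 3 libraries of 1 genotype would not be listed. The recovered totals ranged from 8102605 to 10455908 reads per library. A gene with 0 reads in a library may have up to 3 reads' worth of expression there, a normalised read count of 2.46 to 3.25, and such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. With 200 cells per library, values can also vary between libraries by sampling of transcripts. Genes without a symbol numbered 444 and took 2.22% to 2.38% of reads, and they were kept in the tests. No 2 libraries of a genotype differed by less than sampling noise (lowest chi-square per degree of freedom 82.9).

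The design fixed before the data were examined assumed raw counts and an edgeR quasi-likelihood test. Because the values were already divided by size factors, the main test was limma-trend on log2(value + 1), with genotype as the only term and all 6 libraries in the fit. That choice was made after the values were seen. Genes with a mean value of at least 10 were tested (10846), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is the difference of mean log2(value + 1). The added 1 understates the change of low genes, while a library at or near 0 pulls a group's mean log value down, so that the fold change can exceed, or differ in sign from, that of the group means. edgeR's quasi-likelihood test, the main test of the design, was run on the recovered reads as an alternative. It called 2 genes, S100a8 and Ngp, and neither Car1 nor S100a9, which limma-trend called.

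Before the data were examined, 39 gene lists were fixed (pathways, complexes, markers of other cell types and quality measures), of which 38 had at least 3 tested members. They were tested with camera at a preset correlation of 0.01 between genes. By camera 11 lists passed, 8 up and 3 down. With an estimated correlation none passed after adjustment, and 8 had an unadjusted p under 0.05. Fry, which tests whether the genes of a set move on balance one way and does not compare the set with other genes, passed 4 lists: mitosis (adjusted p = 0.0011), DNA damage response (0.012), neutrophil and granule (0.019) and ribosome biogenesis (0.034). The median, mean and test differed in sign for 8 lists, none of them among the 11. Counts "adjusted over the list alone" use Benjamini-Hochberg within a list.

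Genes were named by a rule fixed before the data were examined. Mcph1 came first, then up to 12 genes with the smallest p in each direction among those past the threshold whose groups do not overlap, leaving out predicted models and pseudogenes. Where fewer than 5 passed in a direction, the genes with the smallest p were named up to 5. Up to 4 members of each described list and 15 genes fixed by name were added. Some genes that the rule names are not reported here. Of the fixed genes, Angpt2 and Xist are not analysed here. Mpo, Elane, Cd48, Anxa1, Hba-a2, Hbb-bs and Hbb-bt were named after their values were seen.

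Positions come from the GENCODE annotation of mm10 (release vM21), matched by gene identifier for 96.2% of the listed genes, and are 1-based. As no strand setting is given, genes that share exonic sequence with another gene are uncertain. Among named genes these are Mcph1, Ddx39a, Ube2c, Ppp2r1b, Grcc10, Rfc4, Rfc5, Ccna2, Cdk6, Parp1, Tapbp, Nhp2, Ripk1, Cdkn1a, Cdkn1c, Agpat5, Cd34, Usp18, Mpo and mt-Nd1.

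The limma, edgeR and DESeq2 gene tests and the camera list test at the preset correlation were run on simulated reads. These were drawn once per setting from the means, library sizes and edgeR gene-wise dispersions of these libraries. The 200 changed genes came from those with a mean value of at least 50, so the detection rates do not cover lower genes. With 200 genes changed, limma (10703 genes tested) called 0 of 50 genes changed 2-fold, 7 of 50 changed 4-fold, 22 of 50 changed 8-fold and 23 of 49 changed 16-fold, and 1 unchanged gene. edgeR (10451 genes) called 0, 6, 21 and 21 of 49 at each size and 1 unchanged gene. DESeq2 (10702 genes) called 3, 18, 37 and 35 of 50 at each size and 96 unchanged genes among 189 calls. With no gene changed, DESeq2 called 69 genes, limma 0 and edgeR 0. A mitosis list shifted by 1.5 on the log2 scale was fitted at a median of 1.57, with 0 other lists called. Genes were drawn independently of each other, so these simulations cannot show how the list test behaves when genes of a list are correlated.

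The alternatives fixed beforehand were other scalings, other filters, DESeq2, limma-voom with and without sample weights, edgeR with robust dispersion, a fold threshold of 1.5, an adjusted p threshold of 0.1, the replicate number as a block, a GC and length correction (values for 96.4% of tested genes), leaving out mitochondrial and the 20 most abundant genes, and leaving out each library. Trimmed-mean factors and pseudocounts of 16 and 0.5 were added after seeing the data. edgeR on the recovered reads was added then as well, although edgeR was the main test of the design. The fold threshold was tested with limma's treat in place of the edgeR version. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, with figures drawn in matplotlib 3.10.9.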

Results

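Gene expression was measured by RNA-seq in hematopoietic stem cells, the bone marrow cells that renew themselves and give rise to all blood lineages, from wild-type (WT) and Mcph1-/- mice. The cells were sorted from the lineage-negative fraction of bone marrow by surface markers as CD150+ CD34- cells that carried Sca-1 and c-Kit. Each library was made with Smart-seq2, a full-length cDNA method for very small inputs, from 200 sorted cells, with 3 WT and 3 Mcph1-/- libraries. Libraries held 8102605, 8450778 and 8655123 reads assigned to the listed genes in WT replicates 1 to 3, and 9464810, 10455908 and 9484122 in Mcph1-/- replicates 1 to 3. Reads were found for 10274 ± 63.1 of the 11108 listed genes in WT and for 10665 ± 134 in Mcph1-/- (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). The Pearson correlation of log2 values across genes, which are not independent replicates, was 0.655 to 0.692 between Mcph1-/- libraries, 0.548 to 0.578 between WT libraries and 0.565 to 0.615 across genotypes. The labels do not say whether the libraries of a genotype came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

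Mcph1, which encodes microcephalin, a protein of chromosome condensation and the DNA damage response, was read in every library. The gene (ENSMUSG00000039842) lies on the plus strand of chromosome 8 from 18595131 to 18803189 in mm10, and its exons overlap the antisense gene Gm16725. Its normalised read count was 160.5, 341.0 and 34.4 in WT replicates 1 to 3, and 427.8, 37.7 and 233.9 in Mcph1-/- replicates 1 to 3. The log2 fold change (Mcph1-/- over WT) was 0.33 with an SE of 1.25 (limma, adjusted p = 0.958), smaller than the spread between replicates. It was -0.58 without WT replicate 3, -0.39 without Mcph1-/- replicate 1 and 1.34 without Mcph1-/- replicate 2. Which part of the gene was deleted is not given in the sources used here, so a count over the whole gene does not check the genotype, and every direction given for the libraries labelled Mcph1-/- rests on the labels.

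The comparison asked which transcripts differ between the stem cell libraries labelled WT and those labelled Mcph1-/-. Of 9 tested neutrophil and granule genes, S100a8, Ngp and S100a9 were far lower in the libraries labelled Mcph1-/-, and the other 6 did not pass over all genes. S100a8, a subunit of the calcium-binding protein calprotectin, fell from a normalised read count of 22359 ± 7481 in WT to 224 ± 91.8 in Mcph1-/- (SD, n = 3), with a log2 fold change of -6.66 (SE 0.34; limma adjusted p = 3.9e-04). Ngp, neutrophilic granule protein, fell from 13645 ± 3353 to 6.75 ± 8.15, with a log2 fold change of -11.33 (SE 0.83; limma adjusted p = 0.0037). S100a9, the other calprotectin subunit, fell from 4919 ± 1080 to 44.3 ± 40.8, with a log2 fold change of -7.22 (SE 0.74; limma adjusted p = 0.024). Camp, the precursor of the antimicrobial peptide cathelicidin, stood at 12992 ± 2638 in WT and 68.8 ± 65.5 in Mcph1-/- but did not pass over all genes (log2 fold change -8.41, SE 1.01; limma adjusted p = 0.060). S100a8 lies on chromosome 3 from 90668978 to 90670035 and S100a9 from 90692632 to 90695721, while Ngp lies on chromosome 9 from 110419747 to 110423012 and Camp from 109847379 to 109849617 (mm10).

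Of 17 genes in the neutrophil and granule list, 9 were tested, of which 8 were lower and 1 was higher in Mcph1-/- by the mean of log2 values. The others, Ctsg, Ltf, Lcn2, Fcnb, Chil3, Cebpe, Mmp8 and Retnlg, have no values here. A granule gene read only in the 3 WT libraries would be missing in this way, so the tested members may not represent the list. Of the tested members, 3 passed over all genes and 4 passed when adjusted over the list alone. The list's median log2 fold change was -4.68 (camera adjusted p = 2.0e-09; adjusted p = 0.116 with an estimated correlation). The myeloperoxidase gene Mpo, chosen after its values were seen, was high in a single library of each genotype, at 5959 in WT replicate 1 and 4856 in Mcph1-/- replicate 3, and at most 53.3 in the others. It is the 1 member counted higher, although its mean was 1987 in WT and 1637 in Mcph1-/-. Elane, neutrophil elastase, likewise chosen afterwards, stood at 3614 and 8095 in those libraries and at most 138 in the others, and is counted lower although its mean was 1251 in WT and 2700 in Mcph1-/-. The call on S100a9 ended without WT replicate 1, 2 or 3 or Mcph1-/- replicate 1 (limma adjusted p = 0.387, 0.218, 0.129 and 0.167), and that on Ngp without WT replicate 1, 2 or 3 (adjusted p = 0.117, 0.123 and 0.115). The list's median was -3.10 without Mcph1-/- replicate 1 and also without Mcph1-/- replicate 2, -2.11 with a pseudocount of 16, -0.57 by DESeq2 and -0.54 by edgeR, and the list passed in each.

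**Figure D1:**
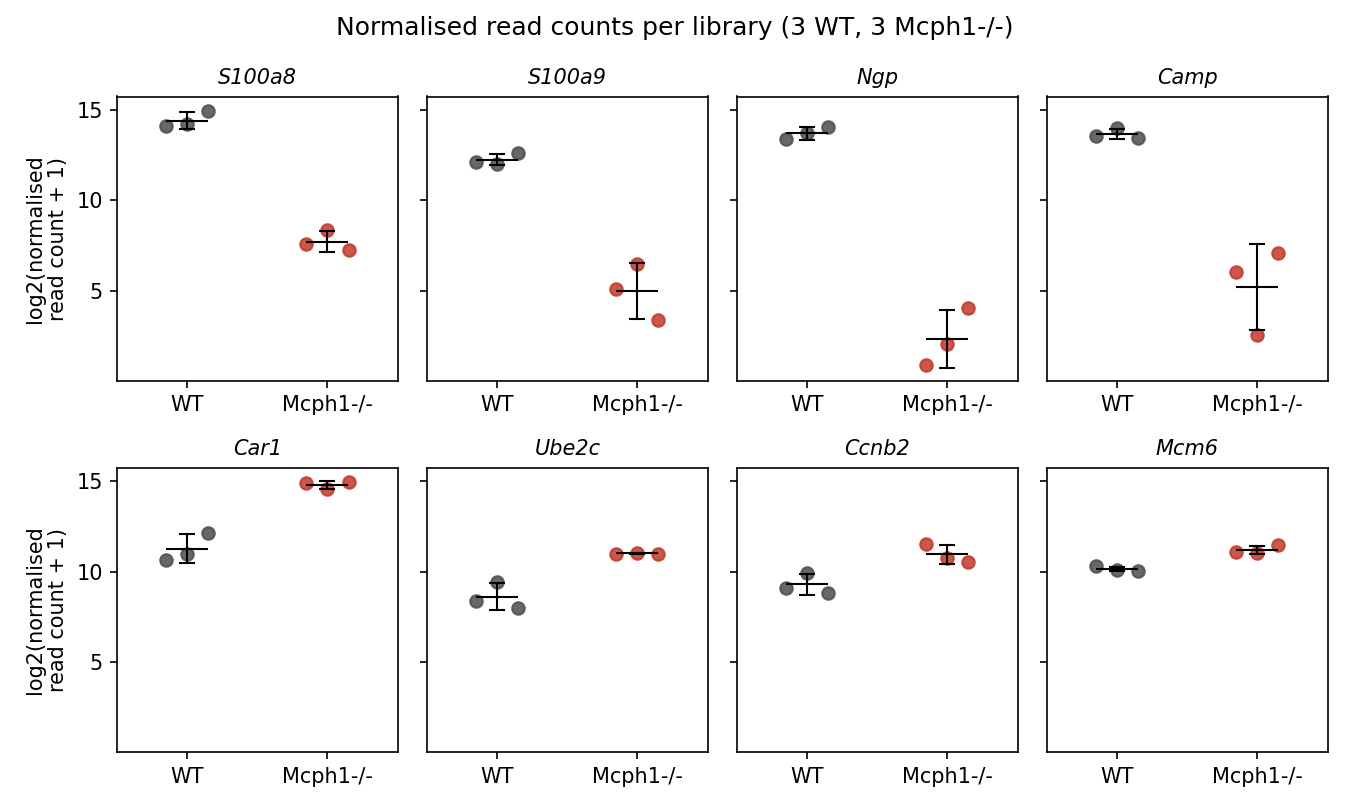
Normalised read count on a log2(value + 1) axis for 8 genes in each of the 3 WT (grey) and 3 Mcph1-/- (red) libraries, 1 point per library, with black bars for the mean ± SD of the log2 values. S100a8, S100a9, Ngp and Camp lie lower, and Car1, Ube2c, Ccnb2 and Mcm6 higher, in all 3 Mcph1-/- libraries than in any WT library; only S100a8, S100a9, Ngp and Car1 passed the test over all genes.

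Car1, carbonic anhydrase 1, an early erythroid enzyme, was the 1 gene that rose past the threshold. Its normalised read count was 2724 ± 1605 in WT and 28533 ± 4268 in Mcph1-/- (SD, n = 3), a log2 fold change of 3.53 (SE 0.35; limma adjusted p = 0.024), or 11.6-fold. It lies on the minus strand of chromosome 3 from 14766216 to 14808368 (mm10). The erythroid list had 13 tested genes, 8 higher and 5 lower, with a median log2 fold change of 0.19, and did not pass (camera adjusted p = 0.109). Over all genes 1 member passed, and 3 passed when adjusted over the list alone. These were Car1, Klf1, the erythroid master transcription factor (log2 fold change 2.40, SE 0.54), and Blvrb, biliverdin reductase B (0.92, SE 0.19). The alpha globin gene Hba-a1 had a log2 fold change of -3.40 (SE 1.21; limma adjusted p = 0.626) and was highest in WT replicate 3, at 8516 against 581 and 251 in WT replicates 1 and 2 and 55.0 to 185 in Mcph1-/-. Hba-a1 and Hba-a2 are near-identical copies whose reads the counting could split, so each is uncertain. Car1 did not pass without WT replicate 1 or 2 or without Mcph1-/- replicate 1, 2 or 3 (limma adjusted p = 0.117, 0.154, 0.189, 0.085 and 0.156), nor by limma-voom (adjusted p = 0.052) or edgeR (adjusted p = 0.133). Without WT replicate 3 the erythroid list's median was 1.27 and the list passed (camera adjusted p = 0.0055), as it did by limma-voom and edgeR. These calls use the preset correlation. With the correlation estimated from all 6 libraries, 0.495, the list was far from passing (camera adjusted p = 0.778).

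**Figure D2:**
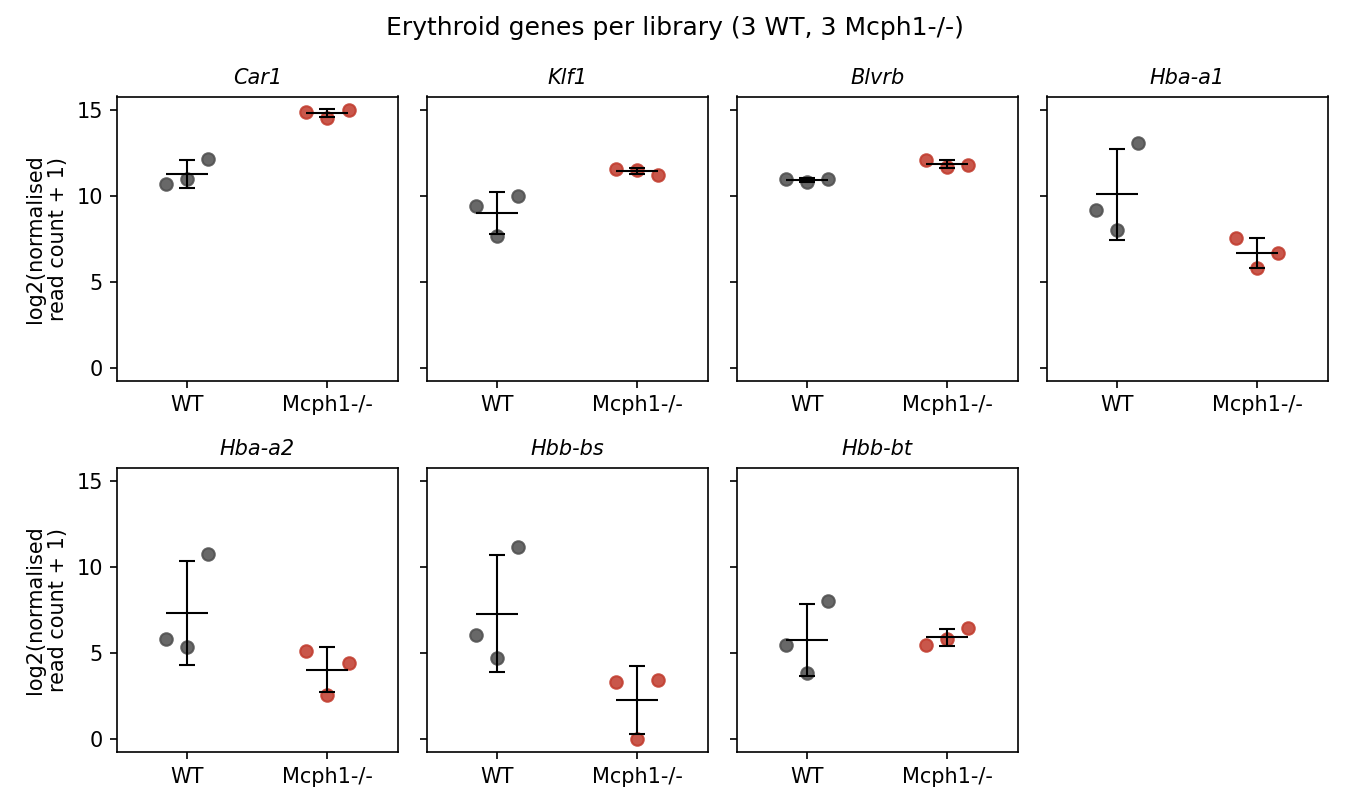
Normalised read count on a log2(value + 1) axis for 7 erythroid genes in each of the 3 WT (grey) and 3 Mcph1-/- (red) libraries, 1 point per library, with black bars for the mean ± SD of the log2 values. Car1, Klf1 and Blvrb lie higher in all 3 Mcph1-/- libraries, while Hba-a1, Hba-a2 and Hbb-bs, which did not pass, lie lower there than in any WT library and are highest in WT replicate 3.

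Transcripts of dividing cells were shifted up as groups. The mitosis list had 36 tested genes, 33 of them higher in Mcph1-/-, with a median log2 fold change of 1.74 (camera adjusted p = 2.0e-09; adjusted p = 0.064 with an estimated correlation). No member passed over all genes, and 4 passed when adjusted over the list alone. They were Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, Kif11, a spindle motor, and the cyclins Ccnb2 and Ccna2. Ube2c stood at 426 ± 232 in WT and 2052 ± 10.8 in Mcph1-/- (SD, n = 3), with a log2 fold change of 2.40 (SE 0.39; limma adjusted p = 0.277). Log2 fold changes were 1.65 (SE 0.38) for Ccnb2 and 1.98 (SE 0.49) for Ccna2. Kif11 had 3 reads in all WT libraries and 1084 in all Mcph1-/- libraries, a depth-adjusted ratio of 303 with an exact 95% interval of 103 to 1472 that covers counting error only. The DNA replication list had 44 tested genes, 38 of them higher, with a median of 0.79 (camera adjusted p = 5.8e-06; adjusted p = 0.151 with an estimated correlation). None of its members passed over all genes or when adjusted over the list alone. The smallest p-values belonged to Mcm6 of the replicative helicase (log2 fold change 1.04, SE 0.22), the clamp loader subunits Rfc4 (1.24, SE 0.33) and Rfc5 (1.11, SE 0.32), and Rrm2 of ribonucleotide reductase (2.34, SE 0.68). The Mcph1-/- libraries, in which these and the 6 other lists that passed upward were higher, were also those with more genes detected. They also had higher Car1 (log2 fold change 3.53) and Klf1 (2.40). S100a8 (-6.66) and Lyz2, lysozyme of monocytes and granulocytes (-1.15), were lower there, and Klf1 and Lyz2 did not pass over all genes. These genes do not stand for their lineages, since 5 of 13 tested erythroid genes were lower and 2 of 5 monocyte and macrophage genes higher.

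The DNA damage response list had 29 tested genes, 24 of them higher in Mcph1-/-, with a median log2 fold change of 1.23 (camera adjusted p = 0.0013; adjusted p = 0.151 with an estimated correlation). No member passed over all genes and 1 passed when adjusted over the list alone. Parp1, a sensor of DNA breaks, had a log2 fold change of 1.63 (SE 0.48), and the checkpoint kinase Chek1 one of 5.58 (SE 2.03), which the 0 reads in WT replicates 2 and 3 raise above the ratio of its means, 28.2 in WT and 227 in Mcph1-/-. A list of reported MCPH1 and E2F1 target genes had 7 tested members, 5 of them higher, with a median of 2.90 (camera adjusted p = 0.034; adjusted p = 0.251 with an estimated correlation). None of these passed over all genes and 1 passed when adjusted over the list alone. The lists share 4 genes, Chek1 among them. The target list did not pass without WT replicate 2 (median 1.19, camera adjusted p = 0.127) or Mcph1-/- replicate 1 or 3 (adjusted p = 0.074 and 0.097), with a mean filter of 50 (0.081), with limma-voom with or without sample weights (0.186 and 0.175) or after GC and length correction (0.0501). By DESeq2 the medians were 0.71 for the damage response list and 1.12 for the target list, by edgeR 0.73 and 1.10, and with a pseudocount of 16 that of the target list was 1.53, and both lists passed by DESeq2 and edgeR.

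The ribosome biogenesis, proteasome, antioxidant and mitochondrial genome lists were higher by smaller amounts, while other lists of growth and protein turnover did not pass. Median log2 fold changes were 0.03 for 78 cytosolic ribosomal protein genes, 42 of them higher (camera adjusted p = 0.973), and 0.05 for 64 nuclear genes of oxidative phosphorylation, 37 of them higher (camera adjusted p = 0.508). The lysosome and autophagy list of 24 genes, 11 of them higher, had a median of -0.14 and a mean of 0.12 (camera adjusted p = 0.718), and 0 members of these 3 lists passed over all genes or when adjusted over the list alone. The ribosome biogenesis list had 26 tested genes, 17 of them higher, with a median log2 fold change of 0.35 (camera adjusted p = 0.010; adjusted p = 0.162 with an estimated correlation). None passed over all genes, and 3 passed when adjusted over the list alone: Nhp2, a core protein of box H/ACA ribonucleoproteins (0.96, SE 0.19), the nucleolar chaperone Npm1 (0.69, SE 0.17) and the nucleolar phosphoprotein Nolc1 (0.87, SE 0.23). The proteasome list had 31 tested genes, 24 of them higher, with a median of 0.20 (camera adjusted p = 0.021; adjusted p = 0.182 with an estimated correlation). Psmd12 (0.65, SE 0.23) and Psmc2 (0.99, SE 0.38) of the regulatory particle had its smallest p-values. The antioxidant list had 21 tested genes, 17 of them higher, with a median of 0.37 (camera adjusted p = 0.021; adjusted p = 0.182 with an estimated correlation), among them the peroxiredoxins Prdx6 (0.54, SE 0.15) and Prdx3 (1.01, SE 0.30). All 7 tested genes of the mitochondrial genome were higher, with a median of 0.52 (camera adjusted p = 0.021; adjusted p = 0.643 with an estimated correlation), led by mt-Nd1 (1.20, SE 0.47). Of 13 mitochondrial genes in the list, 9 have values here, while mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 have none. These 9 took 0.490%, 0.534% and 1.06% of reads in WT and 0.980%, 0.881% and 0.811% in Mcph1-/- (two-sided exact permutation p = 0.4). These shares do not cover the whole mitochondrial genome. No member of the proteasome, antioxidant or mitochondrial list passed over all genes or when adjusted over the list alone. The mitochondrial list did not pass without WT replicate 1 (median 0.21), WT replicate 2 (0.29) or Mcph1-/- replicate 1 (0.42), by DESeq2 (0.35) or after GC and length correction (0.15), and its median was 1.01 without WT replicate 3 and 0.95 with no filter on low values. The proteasome list did not pass without WT replicate 1 (0.14) or Mcph1-/- replicate 3 (0.18) or after GC and length correction (0.11), nor the antioxidant list without WT replicate 3 (0.15) or Mcph1-/- replicate 1 (0.35), and without Mcph1-/- replicate 3 the antioxidant median was 0.57.

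The stem cell identity and antigen presentation lists were lower as groups, although neither passed with an estimated correlation (adjusted p = 0.161 and 0.324). They were lower in the same libraries in which the erythroid genes Car1 and Klf1 were higher (3.53 and 2.40). The myeloid genes S100a8 and Lyz2 were lower there (-6.66 and -1.15), and Klf1 and Lyz2 did not pass over all genes. Other members went the other way: 5 of 13 tested erythroid genes were lower, and 2 of 5 monocyte and macrophage genes were higher. Neither of these 2 lineage lists passed (camera adjusted p = 0.109 and 0.409). The stem cell identity list had 34 tested genes, 22 of them lower in Mcph1-/-, with a median log2 fold change of -0.39 (camera adjusted p = 0.0038). None of its genes passed over all genes or when adjusted over the list alone. Members with small p-values included Pdzk1ip1 (-0.49, SE 0.17), the Myc family gene Mycn (-1.04, SE 0.37) and Mllt3, a subunit of the super elongation complex, (-0.61, SE 0.22). The antigen presentation list had 18 tested genes, 15 of them lower, with a median of -0.37 (camera adjusted p = 2.5e-05). None passed over all genes and 1 passed when adjusted over the list alone. It was the class I gene H2-Q6 (-1.20, SE 0.26), which belongs to a family of near-identical copies and is uncertain. The class I gene H2-T23 had a log2 fold change of -0.61 (SE 0.17) and Tapbp, tapasin of the peptide-loading complex, one of -1.13 (SE 0.45). The identity median was -0.23 without Mcph1-/- replicate 2 and the antigen presentation median -0.23 without Mcph1-/- replicate 3, and both lists passed in those fits.

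**Figure D3:**
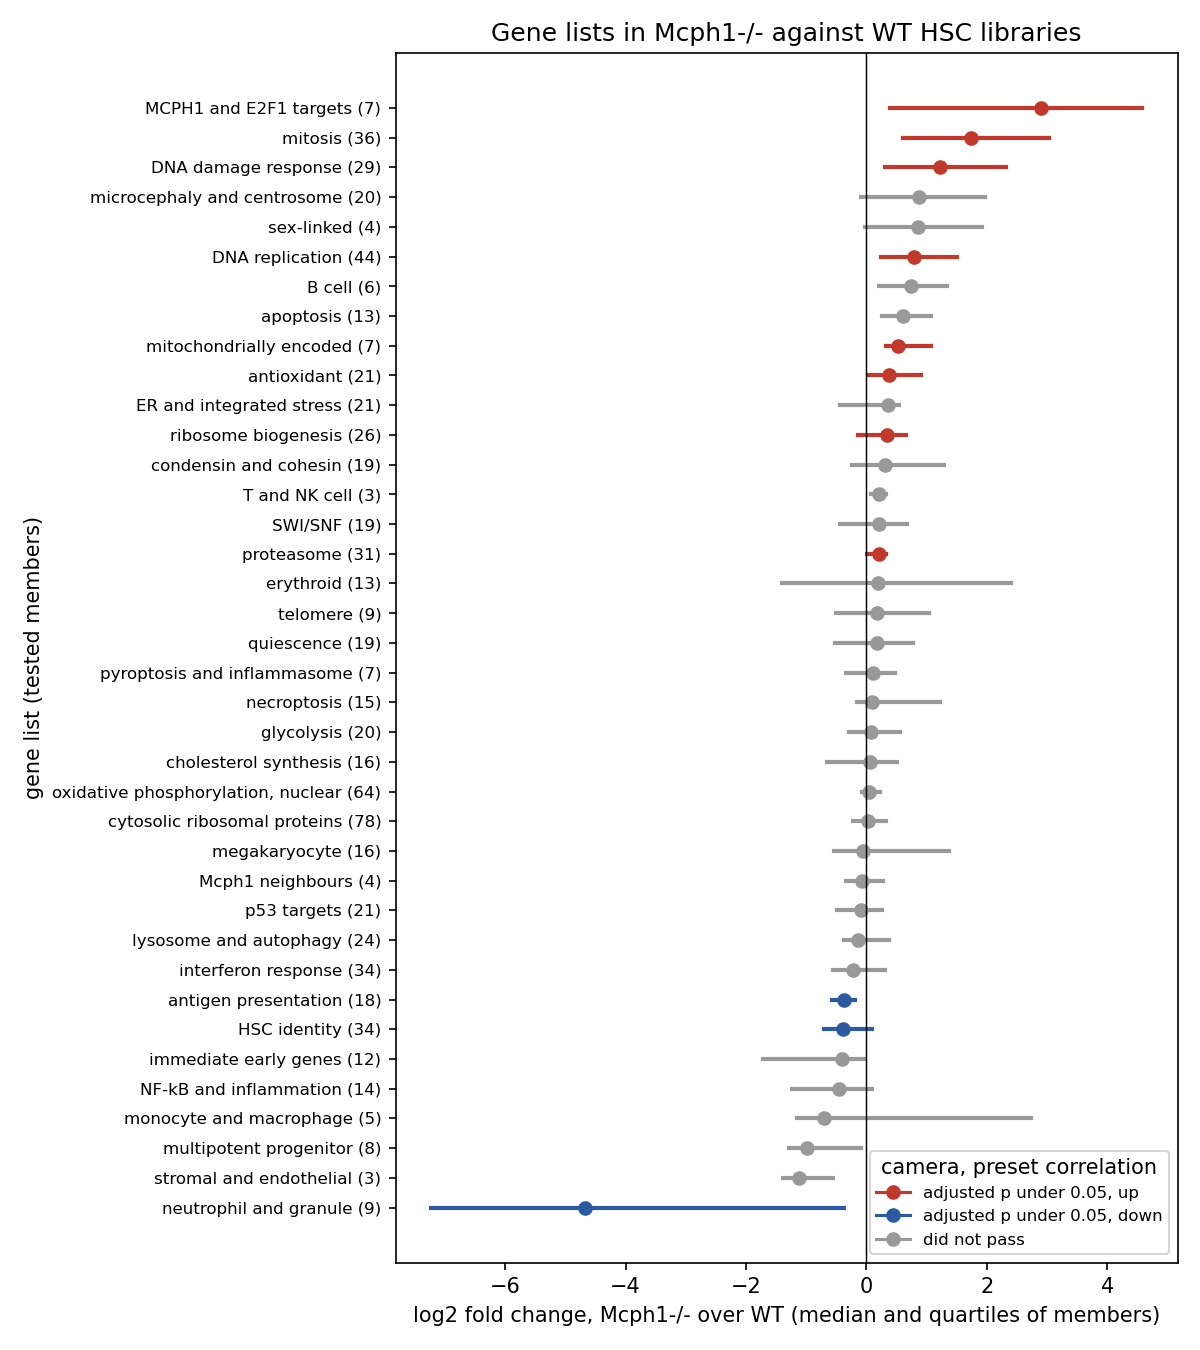
Median log2 fold change (Mcph1-/- over WT) of the tested genes of each of 38 gene lists, with bars for the quartiles of the members; red and blue mark the 8 lists higher and the 3 lists lower past the camera threshold, and grey the 27 that did not pass. The neutrophil and granule list has the lowest median, -4.68, and the MCPH1 and E2F1 target list the highest, 2.90.

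Genes fixed by name before the data were examined did not pass. The necroptosis list of 15 tested genes had a median log2 fold change of 0.09 (camera adjusted p = 0.524), with no member past the threshold over all genes or when adjusted over the list alone. Of its core genes, Mlkl, the executioner pseudokinase, had a log2 fold change of 2.66 (SE 2.12) with means of 204 in WT and 306 in Mcph1-/- and 0 reads in WT replicate 1, and the kinases Ripk1 and Ripk3 had 1.54 (SE 1.18) and 1.25 (SE 0.43; limma adjusted p = 0.626). The cell cycle inhibitors Cdkn1a (0.09, SE 1.52) and Cdkn1c (0.68, SE 1.15) and the proliferation marker Mki67 (1.63, SE 1.22) did not pass either. Genes for the sorting markers had log2 fold changes of -0.39 (SE 2.83) for Slamf1, which encodes CD150, -0.48 (SE 0.38) for Kit, 0.26 (SE 0.30) for Ly6a, which encodes Sca-1, and -0.04 (SE 0.60) for Cd34. Procr, a stem cell surface receptor, had 0.23 (SE 0.48), Agpat5, a neighbour of Mcph1, 0.12 (SE 0.33), and the Y-linked Ddx3y 1.21 (SE 1.01).

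Of 10846 tested genes, 4 passed in limma, 1 higher and 3 lower in Mcph1-/-, and 836 had an unadjusted p under 0.05, 451 higher and 385 lower. The values of all 3 libraries of a genotype lay above those of the other for 14.2% of tested genes, against 10% by chance for 3 against 3. The next smallest p-values, none of which passed, belonged to the RNA helicase gene Ddx39a (log2 fold change 1.32, SE 0.21), Ube2c, the metallothionein gene Mt1 (1.58, SE 0.26) and the phosphatase scaffold gene Ppp2r1b (1.91, SE 0.33) among higher genes, and to Camp and Grcc10 (-1.02, SE 0.17) among lower genes. DESeq2 on the recovered reads called 120 genes higher and 117 lower, the 4 limma genes among them, edgeR called 0 higher and 2 lower (S100a8 and Ngp), and limma-voom called none. Leaving out 1 library gave 0 higher and 1 lower (without WT replicate 1 or 2), 2 and 1 (WT replicate 3), 0 and 2 (Mcph1-/- replicate 1) or 0 and 4 (Mcph1-/- replicate 2 or 3).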

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

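Trimmed-mean scaling and pseudocounts of 16 and 0.5 were chosen after seeing the data, and so was limma-trend as the main test. edgeR's quasi-likelihood test was the main test of the design, and only its use as an alternative on recovered reads was decided afterwards. Car1 and S100a9 did not pass by edgeR. The main limma test called 1 gene higher and 3 lower. DESeq2 called 120 higher and 117 lower, limma-voom 0 and 0 (899 genes at an unadjusted p under 0.05), limma-voom with sample weights 0 and 0 (914 genes), and edgeR 0 higher and 2 lower with robust dispersion (581 genes) and without (586 genes). Without 1 library the counts ranged from 0 to 2 higher and from 1 to 4 lower. In 1 simulated draw with no change DESeq2 called 69 genes. Of its 237 calls here 43 had a library at 0 reads and 236 had groups that do not overlap. Calls at 3 against 3 select for such groups, so this does not tell true calls from false ones. The cause of the differences between tools was not tested. The Mcph1 log2 fold change was -0.58 without WT replicate 3 and -0.39 without Mcph1-/- replicate 1, within a range of -0.58 to 1.34 over the libraries left out. Of the lists, 11 passed by camera, 0 with an estimated correlation, 4 by fry and 8 to 12 without 1 library. Over the alternatives, S100a8 ranged from -6.98 to -6.40 and lost its call only in limma-voom with and without weights, Car1 ranged from 3.24 to 3.98, Ngp from -12.19 to -9.26 and S100a9 from -7.97 to -6.43. The calls on called genes were kept in 74 fits and lost in 26, those on called lists were kept in 242 and lost in 21, and none changed direction. The mitosis, DNA replication, DNA damage response, ribosome biogenesis, stem cell identity, antigen presentation and neutrophil lists passed in all 24 alternatives at the preset correlation. None of them passed with an estimated correlation. DNA replication, stem cell identity and antigen presentation also did not pass by fry (adjusted p = 0.105, 0.128 and 0.217). Among genes and lists not called, 36 gene fits (30 of them in DESeq2) and 9 list fits passed, and 39 gene fits and 51 list fits changed sign without passing. The fold threshold gives no list value. Same-numbered libraries did not deviate together (r = -0.0139, 0.0176 and -0.0295), and not every library correlated best with its own number. With the replicate block, 1 gene was higher and 2 were lower, S100a9 and the MCPH1 and E2F1 target list did not pass, 7 lists passed up and 3 down, and Mcph1 had the same log2 fold change of 0.33. Depth limits low genes, but not all of the 311 to 857 tested genes with 0 reads in a library are low: Mlkl had 0 in WT replicate 1 and 319 and 294 in the other WT libraries.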

Other observations

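The tests of granulocyte progenitor genes, of cells from outside the CD34- gate and of red cell RNA were chosen after the result was seen. Other lineage genes went both ways. The megakaryocyte list of 16 tested genes had a median log2 fold change of -0.06 and did not pass (camera adjusted p = 0.551), with 0 members past the limma threshold over all genes and 2 when adjusted over the list alone. Among these was Nfe2, a transcription factor of platelet formation, at 6986 ± 1059 in WT and 3703 ± 237 in Mcph1-/- (SD, n = 3; log2 fold change -0.91, SE 0.17; limma adjusted p = 0.320). Gata1, a transcription factor of erythroid and megakaryocyte cells, had a log2 fold change of 5.11 (SE 1.81), with a mean of 87.4 in WT, where 1 library had 0 reads, and 751 in Mcph1-/-. Lyz2, lysozyme of monocytes and granulocytes, stood at 10187 ± 2465 in WT and 4486 ± 124 in Mcph1-/- (log2 fold change -1.15, SE 0.20; limma adjusted p = 0.320), the 1 member of the monocyte and macrophage list of 5 genes that passed when adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.409).

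The microcephaly and centrosome list mixes genes of the same disease class as Mcph1 with other centrosome genes. It had 20 tested genes, 15 of them higher, with a median log2 fold change of 0.88, and did not pass (camera adjusted p = 0.155). Over all genes 0 passed, and 1 passed when adjusted over the list alone: Cdk6, a kinase of the G1 phase, at 1242 ± 189 in WT and 2811 ± 504 in Mcph1-/- (SD, n = 3; log2 fold change 1.17, SE 0.23; limma adjusted p = 0.361). The interferon response list of 34 genes had a median of -0.23 (camera adjusted p = 0.107), with 0 members past the limma threshold over all genes or when adjusted over the list alone. Without WT replicate 2 its median was -0.37 and it passed at the preset correlation (camera adjusted p = 0.0071). With an estimated correlation and all 6 libraries it did not pass (camera adjusted p = 0.367). The smallest p-values of the interferon response list belonged to Bst2 (-0.81, SE 0.25) and Usp18 (-1.90, SE 0.63). The quiescence list of 19 genes had a median of 0.17 while its test pointed down (camera adjusted p = 0.988).

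The lower neutrophil granule genes in Mcph1-/- could reflect neutrophil cells or their RNA in the WT libraries. The lineage gate of the sort is meant to exclude such cells, but the purity of the sorted cells was not tested here. A second list of neutrophil genes, of which 7 of 31 were tested and 0 were in a fixed list, had a median log2 fold change of -1.04 (limma's camera over 5 such lists, adjusted p = 0.032; adjusted p = 0.284 with an estimated correlation), and its median was -0.75 without WT replicate 3. Of its members 5 were lower and 2 higher, with quartiles of -2.69 and -0.0028, and its most abundant, Anxa1, stood at 3680 in WT and 1743 in Mcph1-/-, against 22359 and 224 for S100a8 of the first list. Fewer granulocyte progenitor transcripts in Mcph1-/- stays open, since a list of 15 such genes, 7 of them in fixed lists, had a median of -0.33 with quartiles of -1.84 and 1.5, and a median of -0.66 without WT replicate 3. An effect of the genotype within stem cells was not tested apart from these.

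The higher cell cycle lists are unlikely to come only from the larger number of genes detected in Mcph1-/-, since the mitosis median of 1.74 lay above the range of the middle 95% of random lists matched on mean expression, which ended at 0.459, and that of DNA replication, 0.79, above a range that ended at 0.301. GC content and transcript length also do not account for them, as the mitosis list kept a share of 0.912 of its median after correction (1.59, camera adjusted p = 3.7e-09). Cells from outside the CD34- gate stay open: Cd34 had a log2 fold change of -0.037 (SE 0.60) and the multipotent progenitor list of 8 genes a median of -0.99 (camera adjusted p = 0.524), and one of -0.17 without WT replicate 3, with 7 members lower and only Cd48, a marker of multipotent progenitors, higher at 4.05 (SE 1.48). More dividing stem cells in the libraries labelled Mcph1-/- is a hypothesis that these data cannot separate from a different mix of sorted cells. Such a mix also stays open for the lower stem cell identity and antigen presentation lists, for which it was not tested.

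Higher Car1, Klf1 and Blvrb in Mcph1-/- is unlikely to come from red cell RNA there, since the globins, the most abundant red cell transcripts, summed to 272, 114 and 218 in Mcph1-/- replicates 1 to 3, at most a share of 0.00848 of the rise of these 3 genes over their WT means. The counting does record globins, whose sum was 12778 in WT replicate 3. Reads shared by near-identical globin copies may be lost in counting, so each sum may be too low by an unknown amount. The ratio of Car1 to the globin sum was 2.19, 6.02 and 0.357 in WT and 110, 208 and 146 in Mcph1-/-. The globins' own log2 fold changes without WT replicate 3 ran from -3.11 for Hbb-bs to 1.27 for Hbb-bt, with a median of -1.72. A wider erythroid progenitor program may be present but was not resolved, as a second list of 20 tested genes, 13 higher and 7 lower, had a median of 0.17 (limma's camera over 5 such lists, adjusted p = 0.107; adjusted p = 0.284 with an estimated correlation), and one of 0.38 without WT replicate 3.

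The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split, the 1 split with a count as large in each case, gave 4 genes by limma against at most 0 in another split, 11 lists against at most 6, and 237 genes by DESeq2 against at most 61.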
